A study of Macaca mulatta with 100 samples.

How the data were processed

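RNA of blood mononuclear cells, from 49 adult females of the rhesus macaque, was hybridised to Illumina one-colour bead arrays. Per the labels' protocols, RNA was purified on columns with a DNase step, checked on a Bioanalyzer and turned into biotinylated cRNA before hybridisation. The probes were designed on human transcripts, per the annotation columns of the deposited table. The labels give each sample's dominance rank, from 1 (high) to 5 (low), and its animal. The animal was the replicate: 10 animals held each of ranks 1 to 4, and 9 animals held rank 5. The series describes 10 social groups, but the labels do not tie animals to them, so no fit or permutation could hold the group fixed. Age in years and hybridisation slide are not used here either.

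The deposited scanner table holds, per the file headers, an average bead intensity on a linear scale and a detection p-value for each of 47231 probes on each array. No intensity lay below 0, and the lowest was 60.8. Its 100 signal columns were matched to samples by name. 2 of these columns matched no single sample and were not used, which left 98 arrays, 2 for every animal. The authors' deposited value table holds linear intensities of 7303 probes for 100 samples. In 97 of its columns the values were identical to the scanner column of the same name, so its scale was the scanner's own, with no centring and no log. Of the other 3, 2 were identical to the scanner columns that were not used, and 1 to a scanner column of the same animal under another repeat number. Values were not used to assign a column to a sample, so the 2 columns stayed out. The medians of its columns ran from 174.2 to 335.9. How the 7303 probes were chosen is not given in the sources used here. The submitters' processing notes name lumi, without a version. The file's own gene symbols were kept, and some are old. Of the 5241 genes tested, 3923 have a symbol that is also in the table of current macaque gene names. No genome positions are given, because the probes are annotated on another species.

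Intensities of the 98 arrays were background-corrected, quantile-normalized and log2-transformed with neqc in limma 3.58.1 (R 4.3.3, and the package data.table, version 1.17.8, for reading). Negative controls were inferred from the detection p-values, and the offset was 16. The probes tested were those of the authors' value table that were detected (p under 0.01) on at least 18 arrays. This left 6150 probes, of which 5957 carry a gene symbol. Both arrays of an animal were averaged, and all 49 animals entered each fit. As an alternative, the value table, with all of its 100 samples, was taken as log2(value + 16) and quantile-normalized.

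The rank trend was the slope of log2 intensity per step of rank, fitted per probe with lmFit and eBayes in limma. A positive slope means a higher level in lower-ranking animals. Rank was also fitted as a factor with 5 levels. This gave the difference of rank 5 minus rank 1, a moderated F-test over all ranks, a moderated F-test of the departure from a straight line, and the 4 steps between adjacent ranks. A probe passed at a Benjamini-Hochberg adjusted p under 0.05. How far expression as a whole ordered the animals was measured with a ridge regression that predicted each animal's rank from the other animals, with a penalty of 6150, against 99 permutations of rank.

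Before the data were examined, 33 gene lists of cell types, pathways and handling were fixed, together with the tests of rank, most of their alternatives and the rule for named genes. Tests of array batches and of the leading axes were chosen later, as the closing section says. A list's score in an animal was the mean of its genes' values standardized across animals, with 1 probe per gene, the brightest. Its slope on rank was tested with a two-sided permutation test of 100000 permutations, adjusted over the 30 lists with enough measured genes. The dendritic cell, MHC class II and heat shock lists had too few. Members counted below are measured genes, in most lists fewer than were fixed. Measured were 9 of 19 interferon-stimulated, 7 of 15 neutrophil, 4 of 13 monocyte, 3 of 13 B cell and 4 of 22 ribosomal protein genes. Camera in limma was the alternative test, with a preset correlation of 0.01 and with an estimated one. Correlations between animals were tested with 100000 permutations, for which the smallest p is 1e-05.

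The rule named the 10 genes with the smallest p for the trend where no gene passed, and up to 3 members of each list with the smallest p. Up to 3 members were named for the 5 lists with an unadjusted p under 0.05, and 1 for each of the others. That split, and the naming of any gene outside the rule, was made after the values were seen. For the comparisons other than the trend, the rule named genes past the threshold alone, and there were none.

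The trend fit was tested on simulated data. In 20 draws, ranks were shuffled over the animals and 200 of the 6150 probes were given known slopes. Each of the slopes 0.1, 0.2, 0.3 and 0.4 log2 units per step was given to 50 probes. The fit recovered 29.6% of the probes given 0.1, 84.2% of those given 0.2, 96.3% of those given 0.3 and 98.7% of those given 0.4. False calls came to 5.35 per draw on average. The adjustment is stricter when fewer probes change, so these shares hold for 200 changed probes and would be lower for a few. In a single draw with a simulated shift of 0.3 SD per step, 3 of 3 shifted lists passed, with 1 of the 27 others. That shift is larger than any list slope found below (the largest in size was -0.162, for CD8 T cell genes). Smaller list shifts were not simulated.

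Alternatives changed the normalization, the detection filter, the probe set, the threshold, the use of repeat arrays (first, second, or all with animal as a random block), array weights, the variance prior, cell composition covariates, the coding of rank and the animals included. The files give no slide, so no fit had one as a block.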

Results

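Gene expression was measured in peripheral blood mononuclear cells, the fraction of blood that holds lymphocytes and monocytes, of 49 adult female rhesus macaques. The series set out to relate gene regulation to social status, so each animal's dominance rank is the variable of interest. Ranks 1 (high) to 4 were each held by 10 animals and rank 5 (low) by 9. Of the 100 samples in the labels, 98 arrays were used, 2 for every animal. The median bead intensity of an array lay between 98.1 and 148, and the mean share of probes detected lay between 18.6% and 19.1% at the different ranks. The share detected had a slope of -0.0816 percentage points per step of rank (permutation p = 0.327, two-sided, n = 49). The number of animals and arrays limits the precision of all values below.

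Animals differed from each other reproducibly. Across probes, which are not independent replicates, arrays of 1 animal correlated with a median of 0.965 and arrays of different animals with a median of 0.927. The nearest array was the same animal's for 87 of 98 arrays. The intraclass correlation, the share of a probe's variance that lies between animals, had a median of 0.516, and 1109 probes exceeded 0.8. Among the gene lists, it was highest for erythroid genes such as the haemoglobin gene HBD (median 0.969 over 6 genes). B cell genes (0.964, 3 genes), eicosanoid genes (0.96, 5 genes) and neutrophil genes (0.941, 7 genes) followed. Ribosomal protein genes (0.337, 4 genes), oxidative phosphorylation genes (0.279, 7 genes) and cholesterol synthesis genes (-0.0675, 3 genes) were lowest.

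1 set of arrays stood apart from most of the rest. On principal component 3 of the arrays, which held 6.77% of the variance, the 24 arrays of runs 3 and 4, counted in runs of 12 neighbouring columns, had a mean of -16.2 ± 4.38 (SD). The other 74 arrays had a mean of 5.27 ± 5.19 (SD). All 24 animals with 1 array in these runs had their other array outside them, and in 24 of 24 the inside array was the lower. The runs held arrays of 6, 4, 5, 6 and 3 animals of ranks 1 to 5. All 24 arrays in them were the first array of their animal.

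**Figure D1:**
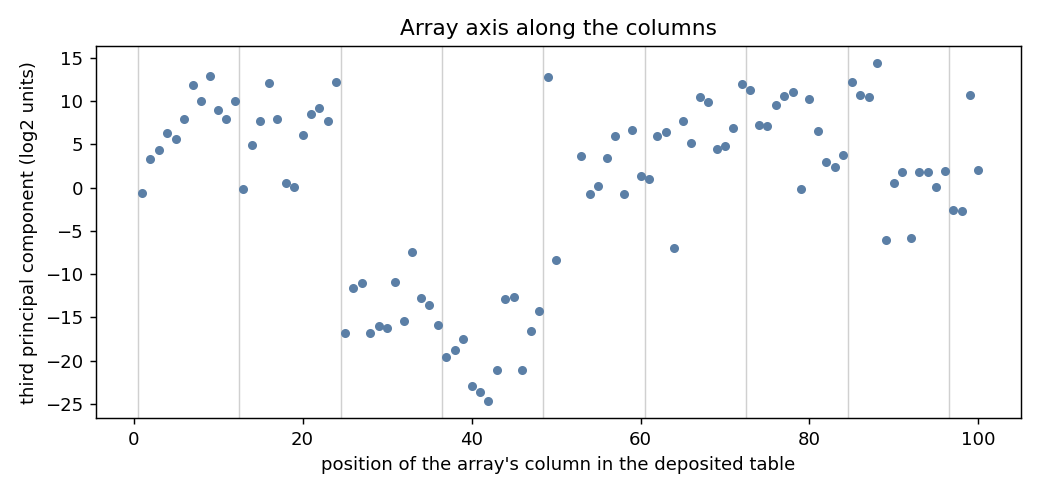
Principal component 3 of the arrays (log2 units) against the position of the array's column in the deposited table. Each point is 1 array and grey lines part runs of 12 columns. The arrays of runs 3 and 4, with a mean of -16.2, lie mostly below the other arrays, with a mean of 5.27. The ranges overlap slightly: the highest array of runs 3 and 4 is at -7.41 and the lowest other array at -8.37.

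The first comparison asked which genes followed the hierarchy from rank 1 to rank 5. The smallest p belonged to BMI1, a component of the Polycomb repressive complex, whose log2 level was 9.32 ± 0.22 (SD, n = 10) at rank 1 and 8.73 ± 0.39 (SD, n = 9) at rank 5. Its slope was -0.14 ± 0.03 (SE) log2 units per step, which corresponds to 0.671-fold from rank 1 to rank 5 (p = 9.06e-05, limma adjusted p = 0.282). RHOBTB3 had a slope of -0.23 ± 0.06 (SE; 0.524-fold; limma adjusted p = 0.457). SLA2, an adaptor that dampens antigen receptor signalling in T cells, had a slope of -0.15 ± 0.04 (SE; 0.662-fold; limma adjusted p = 0.497). No gene passed the test.

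7 others completed the 10 genes with the smallest p, all at a limma adjusted p of 0.497. CHD4, the helicase of the NuRD chromatin remodelling complex, had a slope of 0.10 ± 0.03 (SE), and its other probe had a slope of 0.08 ± 0.03 (SE). OR9A4, an olfactory receptor gene, had a slope of 0.11 ± 0.03 (SE). The 5 with negative slopes were POLR3E, a subunit of RNA polymerase III (-0.19 ± 0.06, SE), ZNF571, a zinc finger gene (-0.13 ± 0.04), OSR2, a zinc finger transcription factor (-0.12 ± 0.04), HCST, the adaptor DAP10 of the NKG2D receptor (-0.08 ± 0.02), and DUSP12, a phosphatase (-0.07 ± 0.02). Several were dim, so their slopes give no exact size: OSR2 was detected on 20 of 98 arrays, OR9A4 and ZNF571 each on 51, and OSR2 at rank 5 on 2 of 18. POLR3E was detected on 13 of 18 arrays at rank 5.

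**Figure D2:**
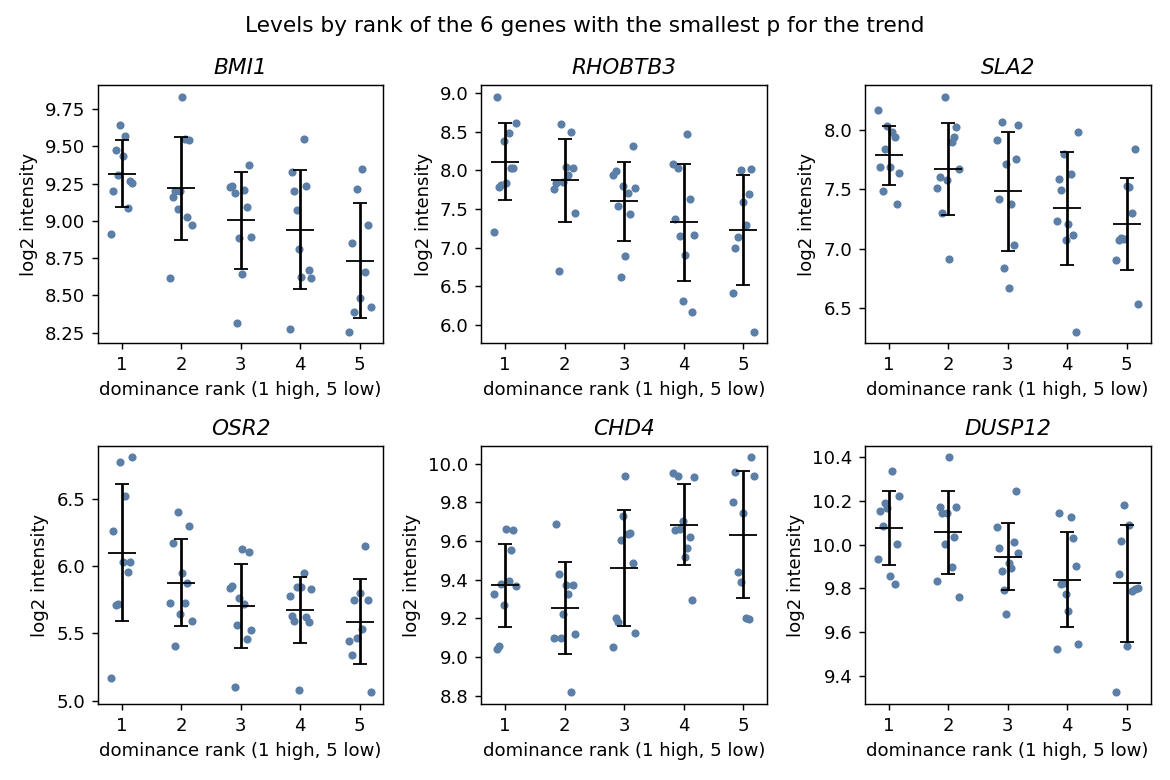
Log2 intensity by dominance rank (1 high, 5 low) of BMI1, RHOBTB3, SLA2, OSR2, CHD4 and DUSP12. Each point is 1 animal (mean of its 2 arrays), bars give the mean and SD of 10 animals, or 9 at rank 5. BMI1 means run from 9.32 at rank 1 to 8.73 at rank 5, with overlapping animals, and none of the 6 genes passed the test.

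Over all 6150 probes, 0 passed at a limma adjusted p under 0.05, and 546 had an unadjusted p under 0.05, against 307.5 expected by chance on average. Probes are correlated, and with ranks shuffled over the animals the count ran from 99 to 1295 (median 216). Of the 546, 369 had a negative slope (lower in lower-ranking animals) and 177 a positive one. The 95% interval of the slope stayed within 0.2 log2 units per step for 90.8% of the probes and within 0.1 for 40.3%. With all arrays entered and animal as a random block, BMI1 and RHOBTB3 passed (2 probes; with a replicate block for the number of the array as well, also 2), a fit that assumes 1 correlation between repeat arrays for every probe. It also counts 98 arrays, although rank varies only between the 49 animals, so its p-values may be too small. In the same fit with column runs as a block, added after the data were seen, RHOBTB3 passed alone. With the first arrays alone, 1 probe passed, of PPP2R2B, named after its values were seen, and with the second arrays alone 0 did. Without the animals of rank 5, the count at unadjusted p under 0.05 was 299. Outside the array runs that stood apart it was 569, with 49 animals, and within them 269, with 24 animals, and 0 probes passed in either.

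Gene lists were then tested along the hierarchy. Cytotoxic lymphocyte genes had mostly negative slopes: 7 of 8 cytotoxic granule genes and 5 of 6 NK cell genes had a slope below 0, with 2 genes of each list at an unadjusted p under 0.05. Granulysin (GNLY), a pore-forming peptide of cytotoxic granules, had a slope of -0.14 ± 0.04 (SE), or 0.681-fold along the fitted line from rank 1 to rank 5. Its mean log2 level was 12.67 at rank 1, 12.79 at rank 2 and 12.24 at rank 5, a difference of -0.43 between the ends. Granzyme H (GZMH), a granule protease, had a slope of -0.18 ± 0.06 (SE), or 0.605-fold along that line, and perforin (PRF1) of -0.09 ± 0.06 (SE). GZMH was at a mean of 13.04 at rank 1, 13.27 at rank 2 and 12.45 at rank 5, a difference of -0.59 between the ends. The granule list's score had a slope of -0.137 ± 0.0626 SD per step (SE, n = 49; permutation p = 0.0343, adjusted p = 0.296). Its mean was highest at rank 2 (0.472), against 0.095 at rank 1 and -0.223 at rank 5. GNLY and GZMH were past the threshold when adjusted over the list alone (both at 0.0224), and 0 of 8 over all probes.

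Of the NK cell receptor genes, KLRD1 (CD94) had a slope of -0.11 ± 0.05 (SE) and KLRC1 (NKG2A), detected on 79 of 98 arrays, of -0.13 ± 0.06 (SE). NCAM1 (CD56) had a slope of -0.12 ± 0.07 (SE). The NK cell score had a slope of -0.132 ± 0.0654 (SE; permutation p = 0.0494, adjusted p = 0.296), with 0 of 6 members past the threshold over all probes or adjusted over the list alone. With rank 5 minus rank 1, KLRD1 differed by -0.24 ± 0.23 (SE) log2 units.

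All 8 T cell genes had negative slopes. CD2, an adhesion receptor of T and NK cells, had a slope of -0.09 ± 0.03 (SE), and the CD3 chains CD3D and CD3G had slopes of -0.05 ± 0.03 and -0.10 ± 0.06 (SE). The T cell score had a slope of -0.138 ± 0.0667 (SE; permutation p = 0.0435, adjusted p = 0.296). CD2 was past the threshold when adjusted over the list alone (0.0465), and 0 of 8 were over all probes. The CD8 T cell pair, with CD8B at -0.10 ± 0.06 (SE), had a score slope of -0.162 ± 0.0943 (SE; permutation p = 0.0927). Naive and helper T cell genes, led by CD4 at -0.06 ± 0.05 (SE), had a score slope of -0.0514 ± 0.0659 (SE; p = 0.439). Over the same animals, neutrophil and erythroid scores had positive slopes, given below.

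Interferon-stimulated genes had positive slopes in 9 of 9 measured members, of 19 genes in the list. IRF7, a transcription factor of the interferon response, was at 5.83 ± 0.43 (SD, n = 10) at rank 1 and 6.97 ± 1.17 (SD, n = 9) at rank 5, with a slope of 0.26 ± 0.09 (SE). It was detected on 5 of 20 arrays at rank 1 and 14 of 18 at rank 5, so rank 1 lay mostly at background and the slope gives no exact size. HERC5, a ligase for the ubiquitin-like protein ISG15, had a slope of 0.22 ± 0.10 (SE). The score had a slope of 0.141 ± 0.0674 (SE; permutation p = 0.0426, adjusted p = 0.296), with 0 of 9 members past the threshold over all probes or adjusted over the list alone. Its mean score was 0.512 ± 0.906 (SD, n = 9) at rank 5 and between -0.237 and -0.000174 at ranks 1 to 4. Camera with a preset correlation called this list (adjusted p = 0.000563), and with an estimated correlation it did not (adjusted p = 0.513).

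Proteasome subunit genes had negative slopes in 9 of 12 members, 3 of them at an unadjusted p under 0.05. The subunits PSMA2 (-0.09 ± 0.04, SE), PSMD1 (-0.09 ± 0.05) and PSMA5 (-0.07 ± 0.03) had the smallest p. The score had a slope of -0.103 ± 0.0475 (SE; permutation p = 0.0351, adjusted p = 0.296), with 0 of 12 members past the threshold over all probes or adjusted over the list alone.

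Myeloid and red cell genes had mostly positive slopes. All 7 neutrophil genes had positive slopes, 1 of them at an unadjusted p under 0.05, the chemokine receptor IL8RB (CXCR2; 0.18 ± 0.07, SE), with a score slope of 0.119 ± 0.0823 (SE; permutation p = 0.157). Camera with a preset correlation called the neutrophil list (adjusted p = 0.0152), and with an estimated correlation it did not (adjusted p = 0.513). All 6 erythroid genes had positive slopes too, 0 of them at an unadjusted p under 0.05, with HBD first (0.25 ± 0.13, SE), with a score slope of 0.106 ± 0.0888 (SE; p = 0.239). Monocyte genes went both ways, with the matrix proteoglycan VCAN at 0.08 ± 0.07 (SE) and a score slope of 0.00499 ± 0.0821 (SE; p = 0.951). Platelet genes, led by GP9 (-0.06 ± 0.07, SE), had a score slope of -0.0498 ± 0.0909 (SE; p = 0.589). B cell genes, with BANK1 at 0.05 ± 0.05 (SE), had 0.0457 ± 0.0769 (SE; p = 0.553). Plasma cell genes, with the surface proteoglycan SDC1 at -0.08 ± 0.04 (SE), had -0.0576 ± 0.0651 (SE; p = 0.381).

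Stress and inflammatory genes did not pass either. Among glucocorticoid-induced genes, the phosphatase gene DUSP1 had a slope of 0.17 ± 0.08 (SE), while 4 of the 6 members had negative slopes and the score had -0.00813 ± 0.0453 (SE; permutation p = 0.857). For genes of the glucocorticoid receptor complex, led by the chaperone HSP90AB1 (-0.04 ± 0.02, SE), the score had -0.0882 ± 0.057 (SE; p = 0.128). NF-kB inflammatory genes, with the adhesion molecule ICAM1 at -0.06 ± 0.05 (SE), had a score slope of -0.0464 ± 0.0599 (SE; p = 0.441). Eicosanoid genes, with the lipoxygenase ALOX5 at 0.17 ± 0.09 (SE), had 0.0607 ± 0.0534 (SE; p = 0.259). Toll-like receptor genes, with TLR2 at 0.13 ± 0.07 (SE), had 0.0743 ± 0.0605 (SE; p = 0.224). Immediate early genes, with FOS at 0.12 ± 0.06 (SE), had 0.0814 ± 0.0584 (SE; p = 0.169).

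Complement genes, with C1QC at -0.14 ± 0.07 (SE), had a score slope of -0.0664 ± 0.0659 (SE; permutation p = 0.318). Genes of MHC class I processing, with B2M at 0.03 ± 0.02 (SE), had 0.0532 ± 0.0643 (SE; p = 0.415). Among genes of T cell receptor signalling, the adaptor LCP2 (SLP-76) had a slope of 0.12 ± 0.04 (SE) and was past the threshold when adjusted over the list alone (0.0398), with 0 of 8 over all probes. That list's score had a slope of 0.0252 ± 0.0473 (SE; p = 0.596). Common gamma chain cytokine genes, with SOCS3 at 0.06 ± 0.04 (SE), had 0.00712 ± 0.0365 (SE; p = 0.847).

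Metabolic and housekeeping lists had score slopes on either side of 0. Hypoxia and glycolysis genes, with the aldolase ALDOA at 0.06 ± 0.03 (SE), had 0.072 ± 0.0497 (SE; permutation p = 0.154). Oxidative phosphorylation genes, with NDUFV2 at -0.05 ± 0.03 (SE), had -0.0742 ± 0.0552 (SE; p = 0.185). Cholesterol synthesis genes, with SQLE at -0.07 ± 0.04 (SE), had -0.0806 ± 0.0639 (SE; p = 0.214). Circadian clock genes, with RORA at -0.09 ± 0.04 (SE), had -0.0834 ± 0.0724 (SE; p = 0.255). Genes of the DNA methylation machinery, with DNMT1 at -0.03 ± 0.03 (SE), had -0.055 ± 0.0563 (SE; p = 0.334). Proliferation genes, with the kinase CDC2 (CDK1) at -0.07 ± 0.04 (SE), had -0.0698 ± 0.0721 (SE; p = 0.336). Ribosomal protein genes, with RPL24 at 0.05 ± 0.04 (SE), had -0.00294 ± 0.0664 (SE; p = 0.965).

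**Figure D3:**
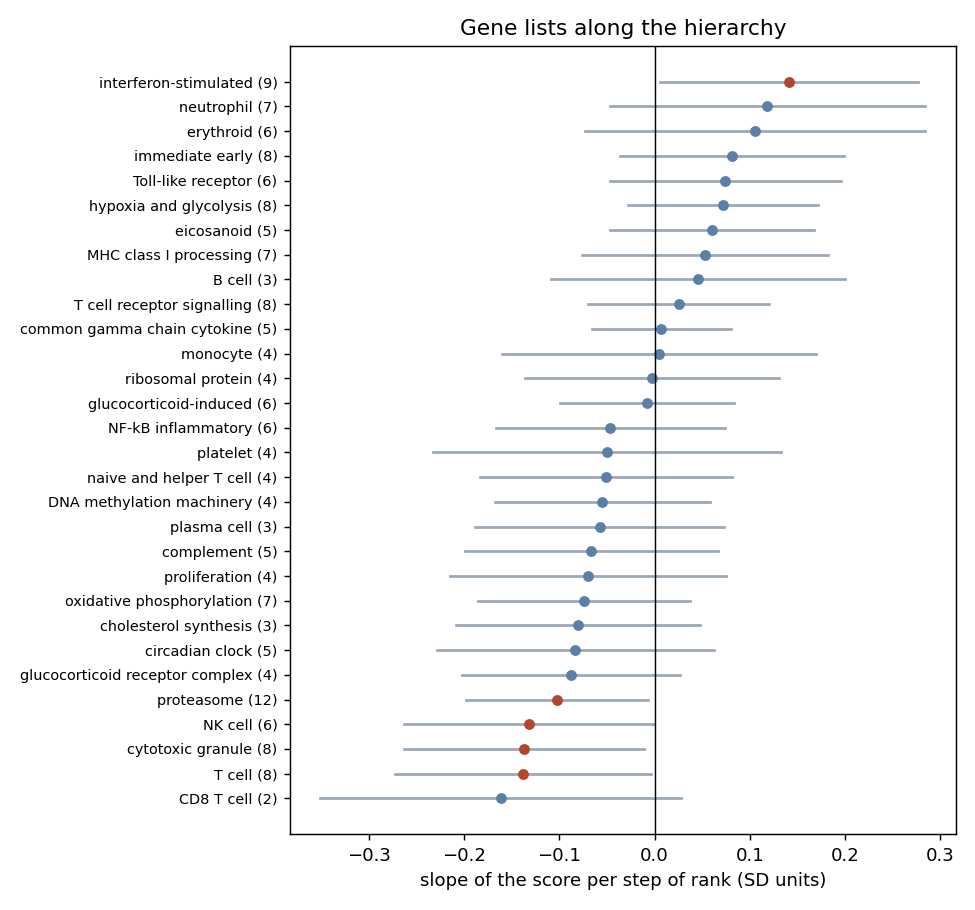
Slope of each list's score per step of rank (horizontal axis, SD units, positive values mean higher in lower-ranking animals) for the 30 lists tested, with the number of measured genes in brackets. Points are slopes over 49 animals and lines their 95% intervals, and red points mark the 5 lists with an unadjusted permutation p under 0.05, from -0.138 for T cell genes to 0.141 for interferon-stimulated genes.

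Several of the members named were dim, so their slopes give no exact size: GP9 was detected on 23 of 98 arrays, BANK1 on 25, CD4 and TLR2 each on 33, SDC1 on 44, DUSP1 on 56, ICAM1 on 60 and CD8B on 64.

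Of the 30 lists, 0 passed the permutation test after adjustment and 5 had an unadjusted p under 0.05, against 1.5 expected. Camera called 2 with a preset correlation and 0 with an estimated one. Over all lists, 4 of 171 members (GNLY, GZMH, CD2 and LCP2) passed adjusted over the list alone and 0 over all probes. The mean, median and test went apart in sign for 3 lists. The score slope of ribosomal protein genes was negative while their median slope (0.02) and camera's direction were positive. For common gamma chain cytokine genes the median slope was -0.01 under a positive score slope, and for glucocorticoid-induced genes camera's direction was positive under a negative score slope.

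The next comparison set the ends of the hierarchy against each other, with no assumption of a straight line. BMI1 differed by -0.58 ± 0.16 (SE) log2 units between rank 5 and rank 1, POLR3E by -0.91 ± 0.26 (SE) and RHOBTB3 by -0.89 ± 0.27 (SE). HERC5 differed by 1.10 ± 0.46 (SE) and HBD by 1.32 ± 0.60 (SE). No gene passed: limma gave 0 probes at an adjusted p under 0.05 (smallest adjusted p 0.742) and 411 at an unadjusted p under 0.05, of which 277 had a negative and 134 a positive difference. Under other settings this count ran from 172 (of 2865 probes detected on every array) to 687 (of 10493 probes), and it was 265 with the first principal component of the animals as a covariate, added after the data were seen. Without animal 1 of rank 1, 1 probe passed.

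Ranks were also compared for differences of any shape. The rule named no gene here, so the levels given are those of genes named above, and they are no result of this test. CHD4 was at 9.37 ± 0.22 (SD, n = 10) at rank 1, 9.25 ± 0.24 (SD, n = 10) at rank 2 and 9.46 ± 0.30 (SD, n = 10) at rank 3. It was at 9.68 ± 0.21 (SD, n = 10) at rank 4 and 9.63 ± 0.33 (SD, n = 9) at rank 5. HERC5 lay between 8.58 and 8.64 at ranks 1 to 4 and at 9.74 ± 1.02 (SD, n = 9) at rank 5. POLR3E lay between 7.52 and 7.85 at ranks 1 to 4 and at 6.93 ± 0.89 (SD, n = 9) at rank 5, where it was detected on 13 of 18 arrays. The moderated F-test over the 5 ranks in limma gave 0 probes at an adjusted p under 0.05 and 179 at an unadjusted p under 0.05 (66 of 2865 probes to 334 of 10493 under other settings). The test of departure from a straight line gave 0 and 101. On average, chance would give 307.5 at an unadjusted p under 0.05 in each, but probes are correlated and such counts spread widely. With ranks shuffled over the animals, the trend count ran from 99 to 1295 (median 216). That spread was not computed for the F-tests or the steps, so counts below the average are not read as a lack. Under other settings, the count for the departure ran from 25 (of 2865 probes detected on every array) to 233 (arrays of runs 3 and 4 alone). Over the 4 steps between adjacent ranks, 0 probe and step pairs passed in limma and 595 had an unadjusted p under 0.05, against 1230 expected, and between 187 (of 2865 probes) and 1143 (of 10493 probes) under other settings. The step from rank 4 to rank 5 had the most of these, 211, and that from rank 3 to rank 4 the fewest, 92. Without animal 3 of rank 2, or without animal 7 of rank 1, 1 pair passed.

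Expression as a whole was asked to order the animals. Animals of rank 1 were placed at a mean of 2.98 ± 0.439 (SD, n = 10) and animals of rank 5 at 3.07 ± 0.406 (SD, n = 9). Ranks 2, 3 and 4 were placed at means of 2.81, 2.97 and 2.95, each below rank 1. Predicted and actual rank correlated with r = 0.103 (one-sided permutation p = 0.08) and rho = 0.124 (one-sided permutation p = 0.1, n = 49). Without the 2 predictions farthest from the median, r was 0.079. With permuted ranks the median r was -0.147, so a value of 0 is not the level without any link. Predictions missed the actual rank by 1.2 steps on average, and the mean rank of the other animals missed it by 1.22.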

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

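No test in this part was chosen after its result was seen. The levels of the 10 genes with the smallest trend p and the scores of the 30 lists were searched in each rank group for an animal lying far from the others. This gave 11 such values, in 10 animals, over 200 groups, where chance gives about 1 in 20.

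Of the genes, OSR2 was at a log2 level of 5.08 in animal 5 of rank 4, below the 5.58 to 5.95 of the other animals of that rank. POLR3E was at 6.29 in animal 3 of rank 1, below the others' 7.60 to 8.48.

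Lymphocyte scores stood apart in 4 animals. The T cell score was 1.2 in animal 9 of rank 3, against -0.827 to 0.228 in the others. The naive and helper T cell score was -1.29 in animal 5 of rank 3, against -0.2 to 0.897, and -1.47 in animal 7 of rank 5, against -0.257 to 0.487. The plasma cell score was -1.87 in animal 7 of rank 4, against -0.816 to 0.343.

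Another 5 scores each stood apart in 1 animal of a rank. The platelet score was -1.95 in animal 5 of rank 2, against -0.407 to 1.02, and the eicosanoid score was -1.39 in animal 6 of rank 2, against -0.186 to 0.732. The score of the glucocorticoid receptor complex was 1.12 in animal 4 of rank 1, against -0.267 to 0.416. In animal 1 of rank 4, the NF-kB inflammatory score was -1.6, against -0.376 to 0.803 in the others, and the ribosomal protein score was -2.67, against -0.432 to 0.836. No explanation of these values was tested.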

How the results depend on the processing

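The settings with column runs, the leading axis and the neutrophil and erythroid scores were added after seeing the data. No list slope passed in the settings that tested lists. For rank 1 versus 5, any rank difference, departure from a straight trend and adjacent steps, 0 probes passed in every setting with all animals. The trend count of 0 became 2 (BMI1 and RHOBTB3) with all arrays and animal as a random block, 2 with the replicate block for the array number added and 1 with the first arrays alone. With column runs as a block in that fit on all arrays it was 1 (RHOBTB3): BMI1 went from a slope of -0.14 ± 0.03 (SE; adjusted p = 0.0246) to -0.13 ± 0.03 (SE; 0.0866), a smaller slope with the same error. Fits on all arrays assume 1 correlation for all probes and count arrays, although rank varies only between animals, so their p-values may be too small. RHOBTB3 had the same slope, -0.233, in the animal means (SE 0.0587) and in the fit on all arrays (SE 0.0469). Its intraclass correlation was 0.888, against a median of 0.516 over all probes. A shared correlation may thus make its error too small, and its pass is no sign of a larger slope. The cause of the other changes was not tested. Array numbers count repeats and were not taken as a pairing: deviations from the group mean correlated with a median of 0.00735 between other animals' arrays of the same number and -0.0427 of another number, and 76 of 98 arrays were closer to their own number, so a weak effect of the number is possible. The replicate block left 602 probes at unadjusted p under 0.05, against 604 without it. Leaving out 1 animal in turn gave 0 to 0 probes for the trend, any rank difference and the departure, 0 to 1 for rank 1 versus rank 5 and 0 to 1 step pairs. Camera with a preset correlation called 2 lists, interferon-stimulated and neutrophil, and with an estimated correlation 0 (adjusted p = 0.513 for both). The prediction from the 500 most variable probes had r = -0.0274, and 0.00497 to 0.128 in the other settings. Slide as a block was not run, since the files give none.

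Of 1225 gene slopes under other settings, 1208 kept sign and side of the threshold, 5 newly passed and 12 changed sign; of 584 list slopes, 552 kept them and 32 changed sign. None of these had passed, and the cause was not tested. With cell marker scores as covariates, slopes were 0.0132 for CD3G, 0.0265 for PRF1, 0.0071 for DNMT1, 0.00454 for plasma cell, 0.0512 for ribosomal protein and 0.0105 for DNA methylation genes. The monocyte score had -0.0143 with no detection filter, -0.00502 in the second arrays and -0.0280 with array weights. Ribosomal protein genes had 0.00871 in the authors' value table, 0.0445 in the first arrays, 0.0200 with array weights and 0.0178 with column runs as a block. Common gamma chain cytokine genes had -0.0259 with detection on every array and -0.00425 with array weights, and NF-kB genes 0.0114 over all detected scanner probes.

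With the first component as a covariate, slopes were -0.00573 for VCAN, -0.0969 for monocyte, 0.0271 for NF-kB, -0.00673 for eicosanoid, -0.0049 for MHC class I processing, 0.0467 for ribosomal protein and 0.00563 for circadian clock genes. With neutrophil and erythroid scores as covariates, naive and helper T cell genes had 0.000894, monocyte genes -0.0421 and ribosomal protein genes 0.0456. In column runs 3 and 4 alone (24 animals, 1 array each), slopes were 0.0426 for CDC2, 0.0265 for ICAM1, -0.071 for ALOX5, -0.00269 for FOS, -0.011 for ALDOA, 0.0439 for NDUFV2, 0.00899 for PSMD1 and 0.0124 for SQLE. List scores there had 0.0163 for naive and helper T cell, -0.0542 for monocyte, -0.00688 for neutrophil, 0.0635 for NF-kB, -0.0485 for eicosanoid, -0.0241 for MHC class I processing, -0.157 for immediate early, 0.0947 for ribosomal protein, -0.0563 for T cell receptor signalling and 0.0304 for circadian clock genes. Counts at unadjusted p under 0.05 for the trend ran with the probes tested, 242 of 2865 detected on every array and 919 of 10493 on the scanner. For the departure and the step pairs they were 25 and 187 with detection on every array, 199 and 1143 on the scanner, 164 and 910 with cell marker covariates, 180 and 930 with neutrophil and erythroid covariates, and 233 and 947 in runs 3 and 4 alone, and with the first component the departure had 170. With that component the trend had 349 and rank 1 versus rank 5 had 265.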

Other observations

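The tests on column runs, on the array axis, and on batch and granulocytes for the first component, as well as the neutrophil and erythroid covariates and the genes named in the first 2 paragraphs, were chosen after the result was seen. The axis along which animals differed most, the first principal component of the animal means with 21.8% of the variance, had PTGS2 and other genes with wide ranges at 1 end. PTGS2, the inducible cyclooxygenase, ran from a log2 level of 6.25 to 12.2 between animals, CREB5 from 5.78 to 10.6, the gelatinase MMP9 from 6.51 to 11.9 and the haemoglobin gene HBM from 4.89 to 11.6. At the other end, the chemokine CXCL10 ran from 5.12 to 9.34 and GPR132 from 5.12 to 8.31. PTGS2 correlated with the neutrophil score over 49 animals (r = 0.733, rho = 0.714, both permutation p = 1e-05, the smallest they can give, and r = 0.679 without the 2 farthest animals). Of the 30 lists, each set against the axis made without its genes, several went with it about as closely as the neutrophil list weighed below. These were eicosanoid (r = 0.755, rho = 0.773, r = 0.721 without the 2 farthest animals), monocyte (0.712, 0.639, 0.621), circadian clock (-0.734, -0.736, -0.681), NF-kB inflammatory (-0.726, -0.724, -0.684), proteasome (-0.714, -0.686, -0.707) and immediate early genes (0.671, 0.647, 0.603), all with permutation p = 1e-05 and adjusted p = 4.29e-05. T cell genes (r = -0.577, rho = -0.537, r = -0.593 without the 2 farthest animals, adjusted p = 7.5e-05) and erythroid genes (0.459, 0.427, 0.412, adjusted p = 0.00196) followed further down. The axis had a slope of 2.83 per step of rank (permutation p = 0.0978), so it was not tied to rank by the test.

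For 5 probes the animals lay in separate clusters, parted by a gap of over 1.5 log2 units with at least 5 animals on either side. The probe of CCDC134 was at 4.64 to 5.63 in 36 animals and at 8.65 to 12.8 in 13, and its intraclass correlation was 0.997. PIK3AP1, an adaptor of B cell signalling, was at 5.13 to 6.44 in 8 animals and at 8.81 to 11.2 in 41. HLA-DQB1, an MHC class II chain, was at 5.70 to 6.18 in 5 animals and at 7.97 to 12.1 in 44. LOC100134537 had a gap of 1.95 and NAAA one of 1.57. For each of these 5 probes, 0 animals had their arrays on both sides. The high cluster of CCDC134 held 2, 4, 3, 2 and 2 animals of ranks 1 to 5. The probes were designed on human transcripts and were not aligned to a macaque genome here, so whether these values reflect expression or the sequence under the probe was not tested.

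Chance was weighed by shuffling ranks over the animals, 100 splits with the real one included. As 0 probes passed for the trend, rank 1 versus rank 5, any rank difference and the departure from a straight line, and 0 pairs for adjacent steps, 100 of 100 splits gave as many in each, as any split must, so these 5 tests say nothing about chance and cannot exclude it. The highest other splits gave 2, 2, 1 and 9 probes and 900 step pairs. A split that calls 900 pairs may point to a structure of the samples, but what lay behind that split was not tested. For the 5 lists at an unadjusted p under 0.05, 4 of 100 splits gave as many (highest other 5), which is under the 0.05 level. This was 1 of the 3 tests that had an open outcome, and it was not adjusted for their number. No single list passed, and the splits could not hold the social group fixed, so chance is not excluded. For the prediction (r = 0.103), 8 of 100 gave as much (highest other 0.314), and chance cannot be excluded.

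The first pattern weighed is the excess of small p-values for the trend, 546 probes at an unadjusted p under 0.05. In 11 of 100 splits as many arose (highest other 1295, median 216), so chance cannot be excluded. Array batches that follow the runs of 12 columns are argued against as the source of most of the excess. The count in the fit on all arrays was 604 without column runs as a block and 542 with them, against 307.5 expected on average. The runs were assumed after the data were seen and the files give no slide, so batches laid out in another way are not excluded. A granulocyte and red cell content that differs between animals is a candidate explanation, since the count was 305 with neutrophil and erythroid scores as covariates. The planned cell marker covariates left 451 and the first component of the animals, added later, left 349, so the answer depends on the covariates chosen, and each set also takes out any part of a rank effect that runs with it.

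The second pattern is the array axis that parts column runs 3 and 4 from the rest. A difference between animals is argued against, because animal explained a share of 0.322 of the variance of the axis. The column runs explained 0.816 (at most 0.743 with runs started at another column). They were laid out after this axis was seen to break along the columns, so their shares restate the pattern and are no test of it. In 100% of the animals with arrays on both sides the inside array was lower, but these runs were singled out because their arrays lie low, so this restates the pattern. An array batch cannot be told apart from other differences between these arrays, which were all first arrays, as the files give no slide or date. No biological explanation was tested.

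The third pattern is the first principal component of the animals, which the animal means on the first component of the arrays follow (r and rho of 1.000, both permutation p = 1e-05, r = 1.000 without the 2 farthest animals). A batch that acts on single arrays is argued against by that component of the arrays. On it, first and second arrays correlated with r = 0.991 (rho = 0.98, both permutation p = 1e-05, r = 0.988 without the 2 farthest animals). Animal explained a share of 0.994 of its variance and column runs 0.274. Many animals had the same neighbouring columns for both arrays, and a batch shared by an animal's arrays would also give a high r. Such a shared batch is not excluded. Granulocytes left in the mononuclear fraction, which density separation would mostly remove, may contribute: with the 7 neutrophil genes left out of the axis, their score correlated with it at r = 0.778 (rho = 0.728, r = 0.705 without the 2 farthest animals, adjusted p = 4.29e-05 over 30 lists), all 7 in the same direction. The brightest of these were S100A9 at 13.40, CAMP at 12.90 and CSF3R at 12.61, and monocytes also express S100A9 and CSF3R, so a change in monocytes is not set aside. Handling before lysis cannot be told apart, as the immediate early score with the neutrophil score taken out of both correlated at r = 0.411 (rho = 0.45, permutation p = 0.00318, r = 0.522 without the 2 farthest animals), between the bounds set for either answer.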
